A study of Rattus norvegicus with 30 samples.

How the data were processed

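Whole-lung RNA of neonatal rats was sequenced in 30 libraries. Per the labels' protocols, newborn rats were divided at random into a group kept in 85% oxygen and a group kept in room air (21% oxygen). The dams were exchanged between the groups daily, the lung was cleared of the trachea and washed in PBS, and RNA was purified on RNeasy columns and made into libraries with the SMARTer mRNA-seq kit. The treatment and time labels give 10 groups of 3 libraries: 2 oxygen labels on each of 5 postnatal days. The labels state 12 rats in each arm, while each arm has 15 libraries, and no label says that the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Because the check of oxygen-response genes went against the treatment labels, groups are called 85%-labelled and 21%-labelled. The titles of the libraries begin with A in the 85%-labelled arm and with O in the 21%-labelled arm.

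The deposited table holds raw counts per gene, whole numbers with a different total in each library, for 35224 genes, of which 32883 carry rat Ensembl IDs and 2341 carry IDs of the authors' own without an Ensembl entry. The aligner, the counting tool and the annotation are not given in the sources used here. The submitters' processing notes list the mouse builds GRCm38 and mm10, whereas the Ensembl gene IDs in the deposited table are those of rat genes, so coordinates are printed as the table gives them. The rat build is not given in the sources used here. The deposited FPKM values equal the count divided by the deposited gene length and by a scaled library size, which was 0.790 to 1.10 times the library's own total, with a largest relative deviation of 5e-10. The authors' deposited log2 fold changes and p-values cover 13 comparisons between groups, by a test that is not given in the sources used here. The FPKM values and the authors' comparisons were used as checks and for comparison, not for the tests. Gene symbols were taken from the deposited table. Of 16008 symbols among the tested Ensembl genes, 14157 were found in a RefSeq table of the rat assembly GRCr8, which was used for names and not for coordinates.

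Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr, which left 17571 genes, 15133 of them protein-coding, and libraries were scaled by TMM. The quasi-likelihood model with robust dispersions was fitted to the 30 libraries together with 1 mean per group, which leaves 20 residual degrees of freedom. Comparisons were the 2 oxygen labels at each day, their mean over the 5 days, an F test of whether that difference changes between days, day 14 against day 1 within each arm, and an F test of any change between days in the 21%-labelled arm. P-values were adjusted by Benjamini and Hochberg over genes. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 0.5, the size named in the series text, and F tests had no size threshold. Levels are TMM-normalised CPM, given as mean ± SD over the libraries of a group. The SE beside a log2 fold change is the absolute fold change divided by the square root of the quasi-likelihood F statistic. It is an approximation and not a standard error estimated by the model.

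The 42 gene lists of pathways and cell types, the groups, the tests and the rule for which genes are named were fixed before the data were examined, while the lists described at each day were picked after their tests were run. List tests used camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, two-sided and adjusted over the 42 lists within a comparison. Some genes stand in more than 1 list. Named genes were, for each day and the mean, the 5 largest rises and 5 largest falls among called genes with a characterised symbol, a mean log2 CPM of at least 3 and no overlap between the libraries of the day (the same sign at the 5 days for the mean), up to 4 genes with the smallest p from each list described, and Cdkn1a, Sftpc, Eln, Kdr and Mki67. For the difference between days they were the 10 genes with the smallest p. Some genes that meet this rule are not reported here, and they stay in the counts and list tests. Genes with close copies, such as the tryptases Tpsab1 and Tpsb2, may share reads, and their separate values are uncertain because the handling of shared reads is not given in the sources used here.

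The steps were tested on negative binomial counts simulated for the 30 libraries from each gene's mean over the libraries, its dispersion and the library sizes, with changes placed in the 85%-labelled day 14 group. In the day 14 comparison 17325 genes were tested. Of 97 genes changed by 1 on the log2 scale, edgeR called 34, with a median recovered size of 0.927, and of 100 genes changed by 2 it called 78, with a median of 2.02; calls were in the right direction. It called 6 unchanged genes. DESeq2 called 42 and 87 of the changed and 28 of the unchanged genes, the F test 15 and 61 and 3, and camera called 0 of 41 unchanged lists and the 1 changed list. So at this depth, 14951463 to 18074590 counts per library, and with 3 libraries per group, a change of 1 on the log2 scale was called in fewer than 1 of 2 genes. That share holds for a comparison with as few changed genes as were simulated. The simulated genes were independent of each other, so camera was not tested on correlated lists. In the real libraries the cell division list had an estimated correlation of 0.502. The smallest chi-square per degree of freedom between 2 replicates of a group was 6.72, so no pair of libraries agreed within counting noise. The labels do not say that a replicate number marks a shared litter or batch. At day 3, deviations from the group means of same-numbered libraries were correlated above 0.1 in each of 3 pairs (0.138, 0.107 and 0.303). Crossed pairs of replicates 1 and 2 stood close to the first 2 of these, at 0.0972 and 0.0974. The values thus do not settle whether the numbers pair the libraries of that day.

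Alternatives fixed before the data were examined were RLE size factors, no filter on low counts, no size threshold or a test against it, the replicate number as a block, the level of Y-linked genes as a covariate, a fit to the 6 libraries of a day alone, DESeq2 1.42.0, and leaving out each library in turn. Added after the data were seen were the mitochondrial share of counts or the correlation of level with gene length as a covariate, a fit without the 4 libraries above 6% mitochondrial counts, and the 85%-labelled arm in place of the 21%-labelled one in the comparison with postnatal change. Single-gene permutation tests were not used, because 3 against 3 libraries cannot go below an exact two-sided p of 0.1.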

Results

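Gene expression was measured by mRNA sequencing in lung tissue of neonatal rats from an oxygen model of bronchopulmonary dysplasia, the chronic lung disease of preterm infants treated with oxygen. The 30 libraries form 10 groups of 3, labelled as 85% oxygen or as 21% oxygen (room air) on postnatal days 1, 3, 7, 10 and 14. Total counts ranged from 14951463 to 18074590 per library, with a median of 16069831, and 17571 of 35224 genes had enough counts to be tested. Differences are given as the 85%-labelled minus the 21%-labelled group on the log2 scale. A gene is called higher or lower at an adjusted p under 0.05 and a size of at least 0.5. Adjusted p-values are from edgeR's quasi-likelihood test unless another test is named. Mitochondrially encoded genes took 2.65% to 19.2% of the counts of a library.

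Genes long known to rise in hyperoxic rodent lung were examined first, as a check of the treatment labels. They were lower, not higher, in the 85%-labelled libraries at the later days. Cdkn1a, the p53-induced inhibitor of cell division (ENSRNOG00000000521, chromosome 20, 6351458 to 6358864), stood at 29.4 ± 4.37 CPM in the 85%-labelled and at 430 ± 42.4 CPM in the 21%-labelled lungs at day 14 (mean ± SD, n = 3). Gdf15, a stress-induced cytokine (ENSRNOG00000019661, chromosome 16, 20555395 to 20557978), stood at 5.04 ± 0.463 against 137 ± 19.1 CPM at day 14 and at 7.01 ± 1.24 against 286 ± 146 CPM at day 10. Nqo1, an NRF2-driven quinone reductase (ENSRNOG00000012772, chromosome 19, 38422164 to 38437180), was lower at day 1, with 32.2 ± 12.4 against 113 ± 2.4 CPM. At that day 7278 of 17571 genes were called, and 28 with mitochondrial share as a covariate. The list was mixed at day 1, with 5 genes lower and 4 higher (5 and 4 adjusted over the list alone). Of the 17 genes of this list that were tested, 10 were lower at day 10 and 15 at day 14, and none was higher at either day (10 lower at day 10, and 15 lower and 1 higher at day 14, adjusted over the list alone). The list's median difference was 0.10 at day 1, -0.23 at day 3, -0.28 at day 7, -0.87 at day 10 and -2.25 at day 14. The label check thus goes against the treatment labels, and every direction given here rests on the labels as they stand.

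**Figure D1:**
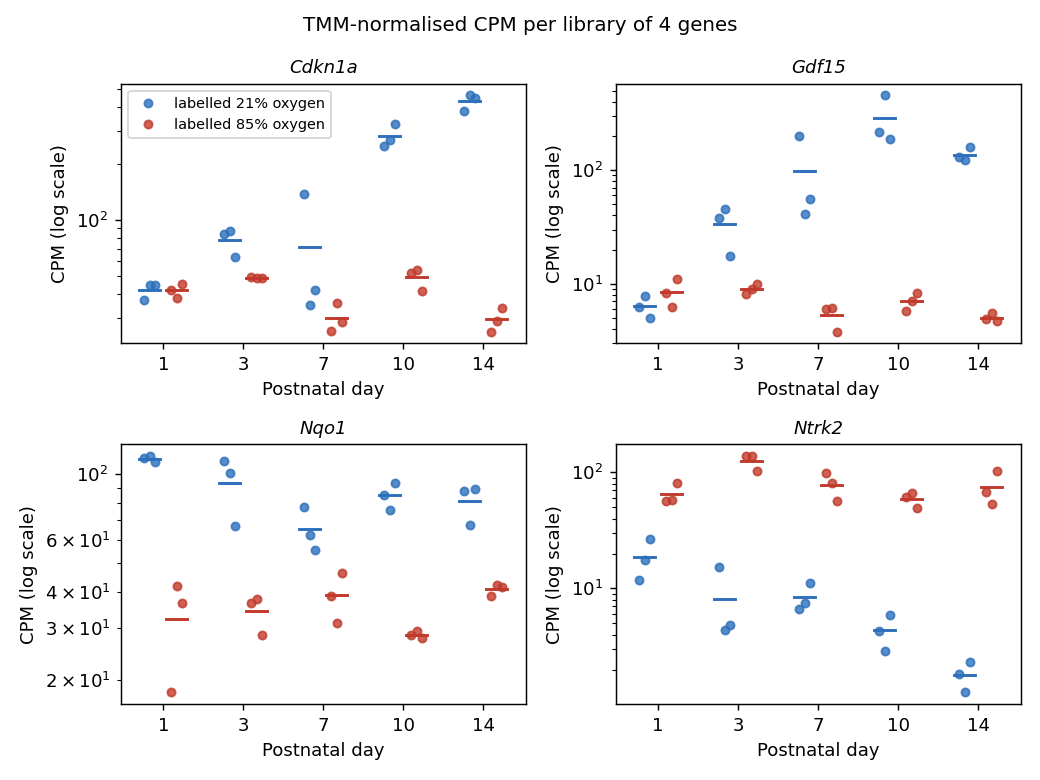
TMM-normalised CPM of Cdkn1a, Gdf15, Nqo1 and Ntrk2 in each library (points, log scale) by postnatal day, with group means as bars and the treatment label by colour. At day 14 the 85%-labelled libraries lie below the 21%-labelled ones for Cdkn1a, Gdf15 and Nqo1 and above them for Ntrk2.

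At day 1, which addresses the first day of exposure, cell division genes and respiratory chain genes were higher in the 85%-labelled lungs and markers of alveolar type 1 cells, the thin gas-exchange epithelium, were lower. These list calls were lost, at adjusted p = 0.858 with an estimated correlation, and the 7278 genes called at this day became 28 with mitochondrial share as a covariate. Of 38 cell division genes, 24 were higher and 1 lower, among them the proliferation marker Mki67 (177 ± 23.6 against 72 ± 12.9 CPM, n = 3 per group) and the spindle factor Tpx2 (1.32, SE 0.20). Of 27 nuclear respiratory chain genes, 15 were higher and 2 lower, including cytochrome c, Cycs (1.30, SE 0.21). Of 14 type 1 cell markers, 7 were lower and none higher, among them Rtkn2 (-3.44, SE 0.65) and the tight junction gene Cldn18 (-1.05, SE 0.20). Kdr, the main VEGF receptor of endothelium, was lower too (-1.15, SE 0.25, adjusted p = 0.00118). Endothelial markers did not move as a set: of 14, 4 were higher and 3 lower (4 and 3 adjusted over the list alone), at a camera adjusted p of 0.728. Of 15 lymphocyte markers, 10 were higher at low levels, such as the T cell receptor component Cd3g (3.95 ± 1.31 against 1.14 ± 0.554 CPM). The largest rises included the cell cycle gene Troap (2.82, SE 0.33), the lipid enzyme Lcat (2.77, SE 0.51) and the mitochondrially encoded ND1 (2.50, SE 0.38) and ND3 (2.55, SE 0.40). The largest falls included Selenbp1 (-5.08, SE 1.47), Tet3 (-4.38, SE 0.85), Soga1 (-4.17, SE 1.06) and Fat4 (-3.90, SE 0.89). Sftpc, the surfactant gene of type 2 cells, stood at 30700 ± 14800 against 14400 ± 2080 CPM (adjusted p = 0.0104).

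In the day 1 lists, the camera adjusted p was 2.55e-05 for cell division, 0.0122 for the respiratory chain, 0.0122 for type 1 cells and 0.0306 for lymphocytes, and each became adjusted p = 0.858 with an estimated correlation. Adjusted over the list alone, 24 cell division genes were higher and 2 lower, 15 respiratory chain genes higher and 2 lower, 7 type 1 markers lower, and 11 lymphocyte markers higher and 1 lower. The mitochondrial share of counts moved with the groups at this day: it was 5.32%, 11.5% and 19.2% in the 85%-labelled libraries and 2.71% to 3.03% in the 21%-labelled ones, as the plot of mitochondrial share shows. The correlation of a gene's level with its length across genes was -0.300 to -0.179 in the former and 0.0999 to 0.190 in the latter. In all, 7278 genes were called, 3624 higher and 3654 lower. With mitochondrial share as a covariate 28 genes were called, 8 of them shared, and Sftpc (-0.82), Lcat (-0.20), ND1 (-0.0095), ND3 (-0.21), Fat4 (0.31) and Soga1 (0.58) took the opposite sign. With the gene length correlation as a covariate 2129 genes were called. Without the 4 libraries above 6% mitochondrial counts, which leaves 1 library in the 85%-labelled day 1 group, 253 genes were called. Sftpc also lost its call without 85%-labelled replicate 1 (0.73) and without 21%-labelled replicate 2 (0.94).

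**Figure D2:**
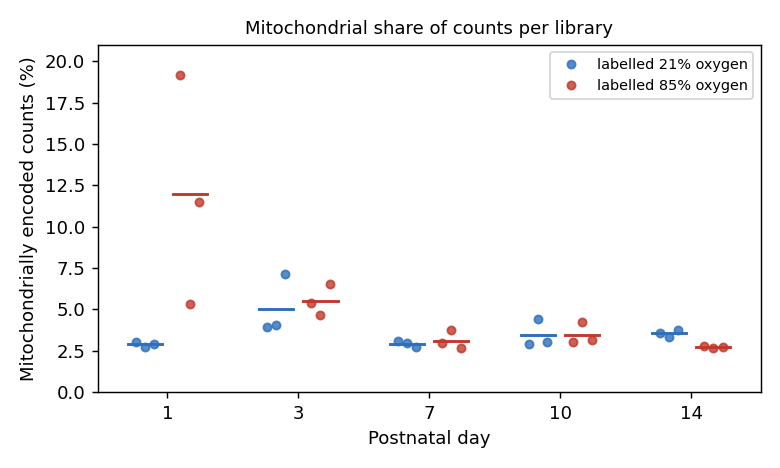
Percent of counts from mitochondrially encoded genes in each library (points) by postnatal day, with group means as bars and the treatment label by colour. The 3 libraries labelled 85% oxygen at day 1 lie between 5.32% and 19.2%, above the 21%-labelled libraries of that day.

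**Figure D3:**
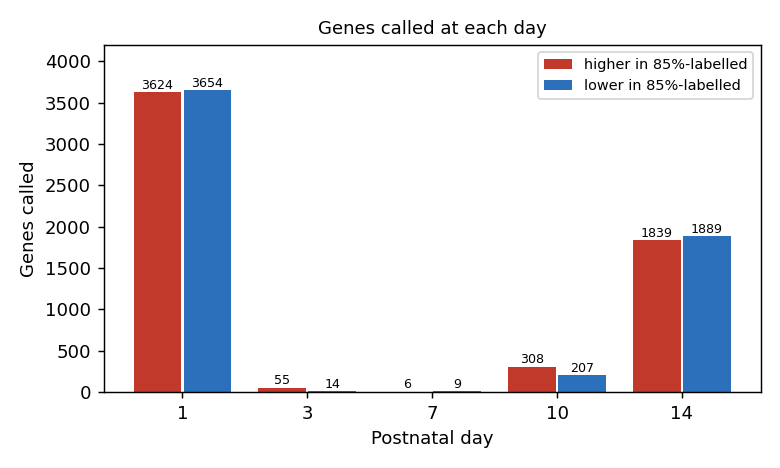
Number of genes called higher or lower in the 85%-labelled than in the 21%-labelled libraries at each postnatal day, 3 libraries per group. Calls peak at day 1 (3624 and 3654) and day 14 (1839 and 1889) and are fewest at day 7 (6 and 9).

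At day 3, red cell and mast cell genes were higher in the 85%-labelled lungs, and a neurotrophin receptor stood out among the other genes. Of 13 erythroid genes, 10 were higher and none lower (12 higher when adjusted over the list alone, median 2.79), such as the anion exchanger Slc4a1 (2.77, SE 0.39), the haemoglobin chaperone Ahsp (2.82, SE 0.45) and Epb42 (2.79, SE 0.35). Haemoglobin genes took 3.48% to 4.94% of counts in the 85%-labelled and 0.481% to 1.67% in the 21%-labelled libraries. Of 10 mast cell and basophil markers, 3 were higher (6 adjusted over the list alone): the mast cell protease Cpa3 (10.1 ± 1.86 against 1.41 ± 0.656 CPM) and the tryptases Tpsab1 (3.59, SE 0.65) and Tpsb2 (3.96, SE 0.74). Ntrk2, the receptor for brain-derived neurotrophic factor (ENSRNOG00000018839, chromosome 17, 5933729 to 6244676), stood at 126 ± 21.2 against 8.13 ± 6.11 CPM (3.95, SE 0.42, adjusted p = 2.43e-05).

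Lower at day 3 were Nqo1 (-1.44, SE 0.22), the glutathione transferase Gsta3 (-2.80, SE 0.38) and Osgin1 (-1.26, SE 0.20), 3 of the 28 genes of the NRF2 and antioxidant list (4 lower and 1 higher when adjusted over the list alone). The lymphatic hyaluronan receptor Lyve1 (-1.03, SE 0.15), 1 of 7 lymphatic markers, was lower too (1 adjusted over the list alone). The camera adjusted p was 1.41e-42 for erythroid genes, 1.57e-10 for mast cells, 0.00313 for lymphatic markers and 9.4e-05 for the NRF2 list. With an estimated correlation the first 3 became 0.000773, 0.0104 and 0.0406, and the NRF2 list became adjusted p = 0.126 with an estimated correlation. Pericyte markers were higher as a list too, at a camera adjusted p of 1.42e-05, and 0.0104 with an estimated correlation. Of these 11 markers none was called over all genes (2 higher adjusted over the list alone). Endothelial markers were higher at a camera adjusted p of 4.4e-06 and oxygen-response genes lower at 0.000359, and each became adjusted p = 0.079 with an estimated correlation. Of 14 endothelial markers none was called over all genes (4 higher adjusted over the list alone). Of 17 oxygen-response genes 1 was lower (3 adjusted over the list alone). Neutrophil and platelet markers were higher at camera adjusted p of 0.000915 and 0.0108, which each became adjusted p = 0.257 with an estimated correlation. In all, 69 genes were called, 55 higher and 14 lower. DESeq2 called 143, 107 higher and 36 lower, and without the 4 libraries above 6% mitochondrial counts, 2 of them of this day, 119 were called, 61 higher and 58 lower. The count was 38 without 85%-labelled replicate 2, 37 without 85%-labelled replicate 3, 27 without 21%-labelled replicate 1 and 32 without 21%-labelled replicate 2. Cpa3 lost its call without 21%-labelled replicate 1 (2.72). Tpsab1 and Tpsb2 lost theirs without 85%-labelled replicate 2 (3.04 and 3.41) and without 21%-labelled replicates 1 (3.46 and 4.13) and 2 (3.63 and 3.54). With the 6 libraries of the day fitted alone, 6 genes were called, and 59 with the replicate number as a block in that fit, 36 of them shared.

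At day 7, Ntrk2 (3.22, SE 0.40, adjusted p = 0.000197) and the incretin receptor gene Glp1r (ENSRNOG00000001152, chromosome 20, 9586075 to 9626228; 39.6 ± 16.3 against 5.23 ± 0.372 CPM) were higher in the 85%-labelled lungs. Gdf15 (-4.21, SE 0.48) and Ptgs2, the inducible prostaglandin synthase (-3.43, SE 0.49), were lower. Lyve1 was lower again (-0.84, SE 0.15), as were the chaperone gene Hsp90b1 (-0.60, SE 0.12), Hnrnpul2 (-0.59, SE 0.12) and Ankrd33b (-1.43, SE 0.29), with adjusted p from 0.0221 to 0.0495. Cdkn1a stood at 29.9 ± 5.33 against 71.8 ± 57.6 CPM and did not pass the test (adjusted p = 0.0965). Of the 17 oxygen-response genes, 1 was lower (4 adjusted over the list alone), with a camera adjusted p of 0.0573 and an adjusted p = 0.665 with an estimated correlation. Camera called erythroid (adjusted p = 0.000265) and ciliated cell genes (0.0368) higher, and cell division genes (0.00244) and genes of VEGF and angiopoietin signalling (0.0202) lower. These list calls were lost with an estimated correlation, at adjusted p from 0.665 to 0.706. No member was called over all genes (3 erythroid genes higher and 3 VEGF and angiopoietin genes lower adjusted over the list alone).

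In all, 15 genes were called at day 7, 6 higher and 9 lower, and 2976 genes had an unadjusted p under 0.05. DESeq2 called 220, 117 higher and 103 lower, and with mitochondrial share as a covariate 521 were called, 177 higher and 344 lower. The count depended on single libraries: it was 761 without 85%-labelled replicate 3, 7 and 8 without 85%-labelled replicates 1 and 2, and 6 and 5 without 21%-labelled replicates 1 and 3. Without any 1 of the day's libraries other than 85%-labelled replicate 3, Lyve1 (-0.85 to -0.70), Hsp90b1 (-0.62 to -0.48) and Hnrnpul2 (-0.58 to -0.42) lost their calls. Ankrd33b lost its call in 4 of these 5 fits (-1.56 without 21%-labelled replicate 3).

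At day 10, genes of stress and inflammation were lower in the 85%-labelled lungs and endothelial genes were higher. Of 24 p53 targets 8 were lower and none higher (11 lower and 1 higher adjusted over the list alone), including Cdkn1a (-2.50, SE 0.32, adjusted p = 5.67e-05), the cyclin Ccng1 (-1.63, SE 0.18) and the nuclease Aen (-1.99, SE 0.22). Of 28 NRF2 and antioxidant genes 10 were lower (13 lower and 2 higher adjusted over the list alone), such as Nqo1 (-1.57, SE 0.22) and haem oxygenase, Hmox1 (-1.20, SE 0.23). Of 25 inflammatory mediators 6 were lower (10 lower and 1 higher adjusted over the list alone), such as the monocyte chemokine Ccl2 (2.04 ± 0.167 against 23.1 ± 13.9 CPM) and Ptgs2 (-2.86, SE 0.46). Of 19 genes of the unfolded protein and ATF4 response 5 were lower (8 adjusted over the list alone), such as Trib3 (-1.50, SE 0.28) and Asns (-1.16, SE 0.20). Of 14 endothelial markers 5 were higher and none lower (9 higher adjusted over the list alone), including the angiopoietin receptor Tek (1.00, SE 0.16) and the adrenomedullin receptor Calcrl (1.47, SE 0.21). Of 8 markers of general capillary endothelium 4 were higher (4 adjusted over the list alone), including Aplnr (456 ± 43.8 against 141 ± 52.2 CPM) and Kit (1.68, SE 0.28). Of 11 pericyte markers, 2 were higher (4 adjusted over the list alone), such as the guanylate cyclase subunit Gucy1a1 (0.80, SE 0.14). Ntrk2 (3.76, SE 0.42), Glp1r (2.84, SE 0.36) and the sodium channel gene Scn7a (2.14, SE 0.32) were among the largest rises, and Gdf15 had the largest fall of the genes named here (-5.35, SE 0.50).

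The camera adjusted p at day 10 was 3.23e-11 for p53 targets, 2.59e-12 for the NRF2 list, 7.99e-07 for inflammatory mediators, 1.84e-08 for the unfolded protein list, 3.12e-10 for endothelium, 3.7e-06 for general capillary cells and 1.59e-06 for pericytes. These calls held with an estimated correlation, with adjusted p from 0.000432 to 0.0101. Immediate early and heat shock genes, which respond to tissue handling, moved with these groups: 7 of 16 were lower (9 adjusted over the list alone), such as Egr1 (-1.47, SE 0.27) and Nr4a1 (-2.08, SE 0.38), with a camera adjusted p of 8.58e-11 and 0.0101 with an estimated correlation. Of 18 macrophage markers 2 were lower (4 adjusted over the list alone), with a camera adjusted p of 0.00268 that became adjusted p = 0.181 with an estimated correlation. Of 6 thymus markers 1 was higher (2 adjusted over the list alone, median 1.72), with a camera adjusted p of 0.000806, and 0.0172 with an estimated correlation. Skeletal muscle and squamous epithelium markers were abundant in 1 library, 85%-labelled replicate 1, with Mylpf at 185 CPM and Krt13 at 94.8 CPM against at most 2.72 and 0.113 CPM in the other 5 libraries of the day. The differences of these genes without that library were 0.48 for Mylpf, 0.07 for Krt13, 0.91 for Krt4, 0.55 for Tnnt3 and -0.27 for Tnnc2. In all, 515 genes were called, 308 higher and 207 lower. The count was 245 and 261 without 85%-labelled replicates 1 and 3 and 170 without 21%-labelled replicate 3. With the 6 libraries of the day fitted alone 9 genes were called, and with mitochondrial share as a covariate 924.

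At day 14, the latest point, stress and inflammatory genes were again lower in the 85%-labelled lungs, and so were macrophage and surfactant genes. Of 24 p53 targets 14 were lower and none higher, including Cdkn1a (-3.87, SE 0.33) and Ccng1 (-2.09, SE 0.19). Of 25 inflammatory mediators 14 were lower, such as the neutrophil chemokine Cxcl1 (-3.39, SE 0.42), Ccl7 (-4.33, SE 0.76) and the iron-binding Lcn2 (-3.41, SE 0.47). Of 18 macrophage markers 16 were lower, including the complement genes C1qa (20.9 ± 1.45 against 103 ± 17 CPM), C1qb (-2.35, SE 0.21) and C1qc (-2.05, SE 0.21). Retnla (-5.77, SE 0.66) and the chitinase gene Chia (-5.18, SE 0.59), both active in type 2 immunity, were among the largest falls. Of 19 unfolded protein and ATF4 genes 13 were lower, such as the chaperone Hspa5 (-1.53, SE 0.19). Of 28 NRF2 and antioxidant genes 19 were lower and 1 higher, such as Hmox1 (-2.25, SE 0.23) and the mitochondrial superoxide dismutase Sod2 (-1.53, SE 0.22). Of 23 surfactant genes 11 were lower, including Sftpa1 (1130 ± 54.1 against 2950 ± 57.9 CPM), Sftpd (-1.11, SE 0.17) and the lamellar body gene Lamp3 (-1.08, SE 0.19).

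Endothelial, capillary, pericyte and fibroblast markers were higher in the 85%-labelled lungs at day 14. Of 14 endothelial markers 9 were higher and none lower, among them Cdh5, the endothelial cadherin (1030 ± 57.1 against 390 ± 32.7 CPM), Calcrl (2.50, SE 0.22) and Tek (1.67, SE 0.16). Kdr was higher too (1.41, SE 0.25). Of 8 general capillary markers 4 were higher and 1 lower: Gpihbp1, which carries lipoprotein lipase on capillaries (16.3 ± 1.17 against 0.68 ± 0.398 CPM), Kit (3.11, SE 0.30), Aplnr (2.25, SE 0.29) and Hpgd (3.66, SE 0.41) were higher and Lpl (-1.46, SE 0.26) lower. Of 11 pericyte markers 4 were higher, such as Gucy1a1 (2.05, SE 0.14) and Pdgfrb (1.03, SE 0.14). Of 15 fibroblast markers 7 were higher and 1 lower, such as Dpt (1.39, SE 0.23) and Slc7a10 (3.79, SE 0.42). Ntrk2 (74.6 ± 25.2 against 1.8 ± 0.526 CPM), Glp1r (4.33, SE 0.37) and the death ligand gene Tnfsf10 (3.77, SE 0.30) were among the largest rises. Elastin, Eln, stood at 15800 ± 1740 against 14900 ± 1710 CPM and Mki67 at 79.7 ± 8.77 against 98.7 ± 8.77 CPM. Neither passed the test (adjusted p = 0.728 and 0.299). Of 38 cell division genes 10 were lower and none higher (12 lower adjusted over the list alone), with a camera adjusted p of 6.7e-05 that became adjusted p = 0.479 with an estimated correlation.

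The camera adjusted p at day 14 was 2.09e-09 for p53 targets, 2.88e-05 for inflammatory mediators, 8.62e-14 for macrophages, 2.43e-10 for the unfolded protein list, 2.44e-08 for the NRF2 list, 8.41e-06 for surfactant genes, 1.21e-08 for endothelium, 0.00141 for general capillary cells, 0.000151 for pericytes and 0.000982 for fibroblasts. These calls held with an estimated correlation, with adjusted p from 0.00148 to 0.041. Adjusted over the list alone, 14 p53 targets, 14 inflammatory, 16 macrophage, 14 unfolded protein, 20 NRF2 and 12 surfactant genes were lower. By the same adjustment 2 NRF2 genes were higher, 9 endothelial, 5 general capillary, 5 pericyte and 9 fibroblast markers were higher, and 1 general capillary and 1 fibroblast marker were lower. Immediate early and heat shock genes moved with these groups, with 13 of 16 lower (13 adjusted over the list alone), such as Egr1 (-3.47, SE 0.29) and Hsph1 (-2.31, SE 0.27), at a camera adjusted p of 1.26e-10 and 0.013 with an estimated correlation. Heart muscle markers moved with the arm too, with 9 of 11 higher (9 adjusted over the list alone), at a camera adjusted p of 0.000196 that became adjusted p = 0.319 with an estimated correlation. Myh6 stood at 37.3, 86.5 and 368 CPM in the 85%-labelled libraries and at 0, 0.182 and 0.122 CPM in the 21%-labelled ones, and Myl7 at 9.23, 23.3 and 113 CPM and at 0, 0.121 and 0 CPM. Mitochondrial share moved with the groups as well, at 2.69% to 2.77% in the 85%-labelled and 3.34% to 3.77% in the 21%-labelled libraries, and so did the correlation of level with gene length, at 0.292 to 0.312 and 0.0292 to 0.232. In all, 3728 genes were called at day 14, 1839 higher and 1889 lower, 4512 with mitochondrial share as a covariate and 3735 with the gene length correlation. Sftpc, at 5600 ± 671 against 11200 ± 1440 CPM (adjusted p = 0.0287), lost its call without 85%-labelled replicate 1 (-1.05), 2 (-1.08) or 3 (-0.92) and without 21%-labelled replicate 1 (-0.96) or 3 (-0.92).

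**Figure D4:**
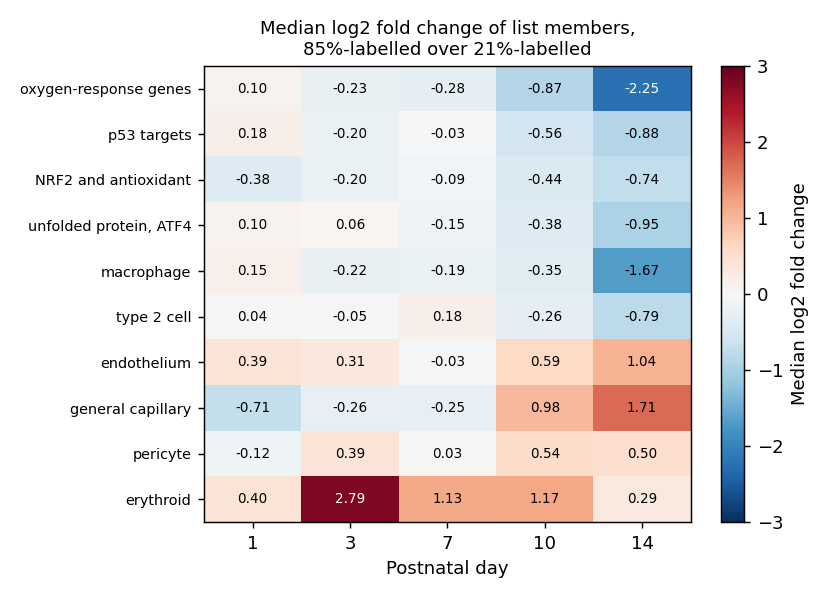
Median log2 difference of the tested members of 10 gene lists at each postnatal day, 85%-labelled over 21%-labelled, with the value in each cell and by colour. The oxygen-response list runs from 0.10 at day 1 to -2.25 at day 14, the general capillary list from -0.71 to 1.71, and the erythroid list has its highest median, 2.79, at day 3.

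Averaged over the 5 days, Ntrk2 (3.62, SE 0.19, adjusted p = 6.49e-12) and Glp1r (2.82, SE 0.16, adjusted p = 1.69e-11) were higher in the 85%-labelled lungs, and both were called at day 1 too (1.80 and 1.75). Vitronectin, Vtn, was also higher (1.87, SE 0.16), and Cdkn1a (-1.66, SE 0.14), the endothelial gene Esm1 (-1.71, SE 0.21) and Gdf15 (-3.16, SE 0.21) were lower. These means do not show an effect common to the course: the day 1 differences of Vtn (0.20), Cdkn1a (-0.01), Esm1 (-0.96) and Gdf15 (0.42) did not pass the test. With 3 libraries per group that does not show that they were absent. For Vtn the difference between the arms changed between days (F test adjusted p = 1.87e-06). Of 17 oxygen-response genes 10 were lower (10 adjusted over the list alone, camera adjusted p = 1.16e-09, and 0.00703 with an estimated correlation). Immediate early and heat shock genes moved with them, with 11 of 16 lower (11 adjusted over the list alone), at a camera adjusted p of 1.77e-08 and 0.0284 with an estimated correlation, as did macrophage markers, with 7 of 18 lower (7 adjusted over the list alone), at 1.62e-07 and 0.0271. Of 14 endothelial markers 5 were higher (5 adjusted over the list alone), such as Calcrl (0.95, SE 0.09) and Egfl7 (1.00, SE 0.11), with a camera adjusted p of 2.17e-07 and 0.0284 with an estimated correlation. Of 15 lymphocyte markers 8 were higher and 1 lower (8 and 1 adjusted over the list alone), such as the B cell gene Cd79b (7.5 ± 2.26 against 3.27 ± 2.16 CPM, SD over 15 libraries), with a camera adjusted p of 7.31e-05 that became adjusted p = 0.207 with an estimated correlation. Other blood and tissue markers moved with them: 12 of 13 erythroid, 6 of 13 neutrophil and 2 of 6 thymus markers were higher (13, 6 and 2 adjusted over the list alone). Their camera adjusted p of 5.98e-09, 0.00828 and 0.0169 became adjusted p = 0.0715, 0.327 and 0.0949 with an estimated correlation. In all, 2339 genes were called, 1110 higher and 1229 lower. The count was 922 with mitochondrial share as a covariate and 1447 without the 4 libraries above 6%.

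Whether the difference between the arms itself changed with age was tested with an F test of whether the effects of the 5 days differ, which called 6613 genes. The endothelial receptor Tek went from -0.79 (SE 0.16) at day 1 to 1.00 (SE 0.16) at day 10 and 1.67 (SE 0.16) at day 14, with an adjusted p of 8.51e-07 for the difference between days. Tnfsf10 went from -0.17 (SE 0.26) at day 1 to 1.95 (SE 0.28) at day 10 and 3.77 (SE 0.30) at day 14, and Prx, a marker of aerocyte capillary cells, from -0.25 (SE 0.20) to 2.99 (SE 0.22). Vtn stood at 0.20 (SE 0.32) at day 1 and 5.98 (SE 0.43) at day 14, and Prxl2a at 0.72 (SE 0.27) and -4.03 (SE 0.31). The potassium channel gene Kcnh2 (1.96), Efcc1 (2.97), Arap3 (1.38) and Rnf144a (1.46) were also higher at day 14, and Ggcx, the vitamin K-dependent carboxylase, lower (-1.03). The test called 3437 genes with mitochondrial share as a covariate, 3360 with the gene length correlation as a covariate and 4104 without the 4 libraries above 6%.

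In the 21%-labelled lungs, the change from day 1 to day 14 took in matrix, p53, macrophage and inflammatory genes, and markers of other tissues fell. The list calls for heart muscle, squamous epithelium and erythroid genes were lost with an estimated correlation, at adjusted p = 0.41, 0.385 and 0.141. Elastin, Eln (14900 ± 1710 at day 14 against 4340 ± 515 CPM at day 1), and the elastic fibre gene Ltbp2 (2.14, SE 0.17) rose. Of 22 genes of the elastin and septation matrix list 8 were higher and 3, including Mfap2 (-1.56, SE 0.23), lower, with a camera adjusted p of 0.0125 and an adjusted p = 0.343 with an estimated correlation. The imprinted growth genes Dlk1 (18.2 ± 8.5 against 1300 ± 101 CPM) and Mest (-4.09, SE 0.45), which decline after birth, were among the largest falls, with Hpgd (-4.04, SE 0.42). Of 25 TGF-beta response and fibrotic matrix genes 19 were higher and none lower, including Ccn2 (3.36, SE 0.36) and Tgfb3 (2.51, SE 0.18). Of 24 p53 targets 13 were higher and 2 lower, such as Cdkn1a (3.34, SE 0.33). Of 18 macrophage markers 14 were higher and 1 lower, such as Adgre1 (3.19, SE 0.31) and C1qa (2.50, SE 0.22). Of 25 inflammatory mediators 12 were higher, such as Cxcl1 (2.66, SE 0.40). Of the 17 oxygen-response genes 12 were higher and none lower (12 adjusted over the list alone), with a camera adjusted p of 1.16e-09, and 0.00305 with an estimated correlation. Immediate early and heat shock genes, which respond to tissue handling, moved with these groups, with 12 of 16 higher (12 adjusted over the list alone), at a camera adjusted p of 1.9e-09 and 0.0258 with an estimated correlation. The camera adjusted p was 2.25e-15 for the TGF-beta list, 1.68e-09 for p53 targets, 1.26e-12 for macrophages and 2.38e-07 for inflammatory mediators, holding with an estimated correlation at adjusted p from 0.00262 to 0.0132. Adjusted over the list alone, 19, 14, 15 and 13 genes of the first 4 lists and 9 of the elastin list were higher, and 2 p53 targets, 1 macrophage marker and 3 elastin genes lower. Of 11 heart muscle markers 6 were lower at day 14, such as Myl7 (13.9, 9.49 and 15.6 CPM at day 1 and at most 0.121 at day 14), of 5 squamous epithelium markers 4, such as Krt4 (15.9, 120 and 25.7 CPM at day 1 and 2.07, 0.424 and 3.24 at day 14), of 13 erythroid genes 10 and of 14 endothelial markers 7, with 1 endothelial marker higher. Adjusted over the list alone, 6, 4, 12 and 7 were lower and 1 endothelial marker higher. Their camera adjusted p of 0.00117, 0.0187, 2.38e-07 and 4e-05 became adjusted p = 0.41, 0.385, 0.141 and 0.107 with an estimated correlation. In all, 3364 genes were called, 1589 higher and 1775 lower. An F test over the 5 days called 9895 genes in this arm, or 6162 with the gene length correlation as a covariate.

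In the 85%-labelled lungs cell division and respiratory chain genes were lower at day 14 than at day 1 and genes of the elastin and septation matrix list higher, list calls that were lost with an estimated correlation, at adjusted p = 0.476, 0.476 and 0.297. Of 38 cell division genes 27 were lower and none higher, of 27 respiratory chain genes 16 were lower and 1 higher, and of 22 elastin and septation matrix genes 15 were higher and 2 lower. The camera adjusted p was 0.000105, 0.000507 and 0.000157 for these lists. The 17 oxygen-response genes, of which 2 were higher and 7 lower, had a camera adjusted p of 0.16. Adjusted over the list alone, 27 cell division genes were lower and 1 higher, 16 respiratory chain genes lower and 2 higher, 15 elastin and septation genes higher and 2 lower, and 7 oxygen-response genes lower and 2 higher. In all, 8981 genes were called, 4407 higher and 4574 lower. The day 1 libraries of this arm are those with the highest mitochondrial shares, and with mitochondrial share as a covariate 593 genes were called, without the 4 libraries above 6% 3236, with 1 library left at day 1, and with the gene length correlation as a covariate 2322. In this arm mitochondrial share and day go together, with 5.32% to 19.2% at day 1 and 2.69% to 2.77% at day 14. The covariate may thus take up part of the change with age, which was not tested.

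The difference between the arms was set against the postnatal change of the 21%-labelled arm, to ask whether it ran along or against that change. This arm stands for normal lung development only if its label holds. Across 17571 genes, the day 14 difference had a Pearson correlation of -0.287 and a Spearman correlation of -0.349 with the change from day 1 to day 10 in the 21%-labelled arm, which shares no library with it. With no filter on low counts the day 14 Pearson correlation was -0.152. At day 7 the correlations were -0.0388 and 0.0524, and the Pearson value ran from -0.0894 to 0.0118 with 1 library left out, so its sign is not settled. Genes are not independent replicates, so no p-value is given. Over the 3723 genes that changed with age, the day 14 value was -0.412 and the day 7 value -0.312. Against the change from day 1 to day 10 in the 85%-labelled arm the values were 0.115 and -0.46. The day 1 libraries of that arm had mitochondrial shares of 5.32% to 19.2%. The main component of the deviations within groups among the 24 libraries of the other days correlated with the day 1 and day 7 differences at 0.757 and 0.524. RNA composition may thus enter the -0.46, which was not tested.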

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

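The tests of RNA composition for the oxygen-response genes and for day 1, the test of an effect of oxygen on RNA composition, the fits with mitochondrial share or gene length correlation as a covariate and the comparison with the change in the 85%-labelled arm were chosen only after the result was seen.

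Genes long known to rise in hyperoxic lung were lower in the libraries labelled 85% oxygen, with a list median below 0 on 4 of 5 days and of -2.25 at day 14. With mitochondrial share as a covariate the day 14 median was -2.15. That argues against a gradient of RNA composition only as far as this share measures it. At day 14 the share coincided with the arm, and the median was not computed with the gene length covariate, so such a gradient stays open. A candidate explanation is that the treatment labels are exchanged between the 2 arms, for which a median below 0 on at least 4 days, here 4, and a lower Cdkn1a were the outcome required in advance. Mean Cdkn1a levels in the 85%-labelled and 21%-labelled libraries were 42.1 and 42.5 CPM at day 1, 49.1 and 78.4 at day 3, 29.9 and 71.8 at day 7, 49.3 and 280 at day 10 and 29.4 and 430 at day 14, and the differences at days 10 and 14 passed the test. Titles that begin with A in the 85%-labelled and O in the 21%-labelled arm could be read as air and oxygen. A real lower level of these genes under 85% oxygen stays open, as untested. A difference in tissue handling stays open too: immediate early and heat shock genes were lower with the list at day 14 and, in 7 of 16, at day 10.

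At day 1, 7278 genes were called, and the mitochondrial share lay above that of each 21%-labelled library of the day in 3 of 3 libraries labelled 85% oxygen. Gene length bias as the whole cause is argued against by the share of genes called among those of middle length, which was 0.955 of the mean share among the shortest and longest genes. A part for it stays open: the difference ran with gene length (Spearman -0.283, medians from 0.485 for the shortest to -0.331 for the longest genes), and 2129 genes were called with the length covariate. A gradient of RNA composition between libraries may account for many of these calls: the main component of the deviations within groups among the 24 libraries of the other days, 30.2% of their variance, correlated with the day 1 difference across genes at 0.757. An effect of the oxygen level itself on the composition of the RNA cannot be told apart from a difference in tissue or RNA handling, because composition and group coincide in these 3 against 3 libraries. The labels give no handling batch that could separate them.

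The day 14 difference had a Pearson correlation across genes of -0.287 with the change from day 1 to day 10 of the 21%-labelled arm, and of -0.152 with no filter on low counts. With mitochondrial share as a covariate the value was -0.261. That argues against a gradient of RNA composition only as far as this share measures it. At day 14 the share coincided with the arm, and the correlation was not computed with the gene length covariate, so such a gradient stays open. Delayed postnatal maturation under hyperoxia may be involved, but other splits of the same 6 libraries gave correlations up to 0.311, 2 of them as large in size, so the direction cannot be told apart from chance. The reading also turns with the labels, and against the change from day 1 to day 10 in the 85%-labelled arm the value was 0.115. A negative value can also come from an arm difference common to days 10 and 14, since the 21%-labelled arm enters the 2 sides with opposite signs.

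The difference between the arms changed with age, by an edgeR F test, for 6613 genes. The smallest adjusted p-values among the genes named by the fixed rule were 8.51e-07 for Prxl2a (0.72 at day 1, -4.03 at day 14) and Tek (-0.79, 1.67), 9.18e-07 for Arap3 (-0.04, 1.38) and Efcc1 (-1.12, 2.97), and 1.3e-06 for Tnfsf10 (-0.17, 3.77) and Ggcx (0.39, -1.03). They were 1.5e-06 for Kcnh2 (-0.39, 1.96) and Prx (-0.25, 2.99), 1.85e-06 for Rnf144a (-0.65, 1.46) and 1.87e-06 for Vtn (0.20, 5.98).

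Other splits of the same libraries were counted for each comparison. Only the real split of 50 gave as many genes, a share under 0.05, for the mean over days (2339 genes, highest other split 1576). The same held for the difference between days (6613, highest other 6053) and the change between days in the 21%-labelled arm (9895, highest other 5706). The count for the difference between days ran from 4670 to 9226 with 1 library left out and was 3437 with mitochondrial share as a covariate. These values reach below the 6053 of another split, so chance is not excluded for this count. The count for the mean over days was 922 with mitochondrial share and 1417 with the gene length correlation as a covariate. Both lie below the 1576 of another split, so chance is not excluded for the mean either. For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real value and the highest other were 7278 and 0 at day 1, 69 and 0 at day 3, 15 and 0 at day 7, 3728 and 1 at day 14, 3364 and 0 for day 14 against day 1 in the 21%-labelled arm and 8981 and 2 in the 85%-labelled arm. At day 10 the real split gave 515 and 1 other split gave 571, so 2 of 10 gave as many. That split puts 85%-labelled replicate 1 with 21%-labelled replicates 1 and 3 against the other 3 libraries and follows a structure of the samples: mitochondrial shares were 3.03%, 2.92% and 3.02% on one side and 4.23%, 3.17% and 4.41% on the other.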

How the results depend on the processing

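The fits with mitochondrial share or gene length correlation as a covariate, the fit without the 4 libraries above 6% mitochondrial counts and the comparison with the 85%-labelled arm's own change were chosen only after the result was seen. Of 260 gene values, RLE size factors in place of TMM left 260 with their direction and call, DESeq2 246 of 256, the replicate number as a block 251, no filter 249, the Y-linked covariate 251, the length covariate 233, the fit without the 4 libraries 230 and the mitochondrial covariate 217. Fits to the day's 6 libraries alone left 146 of 200, and 150 of 200 with the block. Leaving out 1 library kept 2090 of 2232. The cause was not tested unless named.

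With mitochondrial share as a covariate, 28 genes were called at day 1, 108 at day 3, 521 at day 7, 924 at day 10, 922 for the mean, 3437 for the difference between days and 593 for day 14 against day 1 in the 85%-labelled arm; at day 1 the signs of Sftpc (-0.82), Lcat (-0.20), ND1 (-0.0095), ND3 (-0.21), Timp1 (-0.10), Ndufb10 (-0.14), Fat4 (0.31) and Soga1 (0.58) turned. With the length covariate the counts were 2129 at day 1, 1417 for the mean, 3360 for the difference between days, 6162 for change between days in the 21%-labelled arm and 2322 for the 85%-labelled arm. Without the 4 libraries they were 253 at day 1, 119 at day 3, 42 at day 7, 1447, 4104 and 3236 for the mean, the difference between days and the 85%-labelled arm. No filter, the replicate block and the Y-linked covariate gave 8 genes each at day 7. With the day's 6 libraries alone, 4470, 6, 0 and 9 genes were called at days 1, 3, 7 and 10, and with the block in that fit 4556, 59, 0 and 6. The cause was not tested. Where edgeR called 0 at day 7 in the fits of 6, 2976 genes had an unadjusted p under 0.05 in the fit of 30, and DESeq2 called 220 with the 30 libraries. DESeq2 called 143 at day 3. Without the size threshold the mean had 5391 genes. A test against that threshold, stricter by construction, gave 3909, 33, 6, 65 and 1593 on the 5 days in turn, 245 for the mean and 1493 for the 21%-labelled arm.

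Leaving out 1 library gave 27 to 102 genes at day 3 (lowest without 21%-labelled replicate 1, highest without 21%-labelled replicate 3), 5 to 761 at day 7 (21%-labelled replicate 3, 85%-labelled replicate 3) and 170 to 525 at day 10 (21%-labelled replicate 3, 85%-labelled replicate 2); for the other counts each fit stayed within 1.5 times the count with 30 libraries, though the fits ran from 5105 to 8615 at day 1, 1738 to 3247 for the mean and 4670 to 9226 for the difference between days. The day 7 correlation with postnatal change ran from -0.0894 to 0.0118. Tnnc2 at day 10 turned to -0.27 without 85%-labelled replicate 1 and reached 7.43 without replicate 2. Of 210 list tests over the 5 days camera called 64, and 28 with an estimated correlation. The oxygen-response median was below 0 at 4 days by TMM and RLE and at 5 with the mitochondrial covariate. The correlation with postnatal change was -0.287 at day 14 and -0.0388 at day 7; with no filter it was -0.152 at day 14, over changed genes -0.412 and -0.312, and against the 85%-labelled arm's own change 0.115 and -0.46.

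The labels share replicate numbers. At day 3 each same-number pair was correlated above 0.1. There the block in the fit of 30 libraries changed no call of a gene or list described at that day. The ciliated, macrophage and thymus lists, at camera adjusted p of 0.0505, 0.0577 and 0.0577, came to 0.0491 with the block. On the other days not each pair was correlated above 0.1 (day 7: 0.12, 0.0997 and 0.133, with other pairs negative). Of the 15 same-number pairs 8 were (range -0.258 to 0.475), and 9 of 15 85%-labelled libraries correlated best with their own number. As a block they gave 7120, 54, 8, 412 and 3576 genes on the 5 days in turn, so the day 7 count moved by over 1.5 times.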

Other observations

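The tests of the lists described here were fixed before the data were examined, and Col2a1 and the Y-linked genes were chosen after their values were seen.

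Glycolysis and hypoxia-response genes were lower in the 85%-labelled lungs at day 14. Of 23 genes of this list 11 were lower and 1 higher (11 and 1 adjusted over the list alone), including lactate dehydrogenase, Ldha (252 ± 11.1 against 661 ± 34.5 CPM, n = 3), the vasodilator Adm (-2.83, SE 0.30), Gapdh (-1.46, SE 0.21) and the enolase Eno1 (-0.89, SE 0.14). The camera adjusted p was 0.0037, and 0.0188 with an estimated correlation. Fibrosis genes of the TGF-beta list went the same way at that day, with 11 of 25 lower and 1 higher (11 and 2 adjusted over the list alone), such as Ccn2 (306 ± 61.2 against 2160 ± 41.7 CPM), Ccn1 (-2.81, SE 0.28) and Timp1 (-2.04, SE 0.26), at a camera adjusted p of 0.000196 that became adjusted p = 0.113 with an estimated correlation.

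The differences at days 10 and 14, which share no library, went together across 17571 genes with a Pearson correlation of 0.359. Of the called genes, 201 were higher at both days, where independent lists would share 32.2, 163 were lower at both, where they would share 22.3, and 5 were called in opposite directions. Days 1 and 7 had a correlation of 0.476, days 1 and 3 of 0.313, and days 1 and 14 of -0.117. The main within-group component, taken without day 1 libraries, correlated with the differences of days 1, 7 and 3 at 0.757, 0.524 and 0.34. Its correlation was -0.102 at day 10 and -0.165 at day 14. Gene length correlations separated the arms at day 7 too, at -0.276 to 0.281 (85%-labelled) and 0.301 to 0.333 (21%-labelled). Shared RNA composition may thus enter the agreement of days 1, 3 and 7, which was not tested. Ntrk2 and Glp1r were called higher at day 1 (1.80 and 1.75) and at days 3, 7, 10 and 14, and Gdf15, Adm and Ptgs2 lower at days 7, 10 and 14.

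Col2a1, the main collagen of cartilage, stood at 228 CPM in 85%-labelled day 14 replicate 3 and at no more than 0.659 CPM in the other 5 libraries of that day; the same library had the highest level of the heart gene Myh6 at that day, 368 CPM. The Y-linked genes Eif2s3y and Kdm5d stood at 14.5 and 8.8 CPM in 21%-labelled day 3 replicate 3, whereas in the other 29 libraries they were either at most 0.701 and 0.0677 CPM or between 53.3 and 137 and between 41.9 and 83.9 CPM.

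In the authors' deposited table, with an adjusted p under 0.05 and a size of at least 0.5 required as above, 5813, 186, 381, 414 and 4823 genes differed between the arms on the 5 days in turn. Over its 13 comparisons 12808 genes differed in at least 1, where the series text states 17613. The authors' deposited table gives Cdkn1a 3.86 and Gdf15 4.76 at day 14 as the log2 ratio of the 21%-labelled over the 85%-labelled group, and Ntrk2 -5.38.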
